A study of Mus musculus with 4 samples.

How the data were processed

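RNA-seq libraries of total RNA from mouse spermatogonial stem cells were grouped by the treatment in the labels, 2 with doxycycline (10 µg/ml for 2 days) and 2 without. RNA was extracted with TRIzol and sequenced on a HiSeq4000, per the labels' protocols. TopHat2 2.0.6, Cufflinks 2.0.2 and Cuffdiff and the genome build mm9 are named in the submitters' processing notes, which give no role or order for them here. The deposited values are FPKM per gene, 1 table per library in the layout of Cufflinks, per the file headers, and FPKM is scaled by the authors for transcript length and for the mapped fragments of the library. The gene annotation, strand setting and any further scaling by the authors are not given in the sources used here. The tables of each library hold 23021 lines for 22552 symbols, and the FPKM of the 259 symbols on several lines were summed. The table of doxycycline replicate 1 alone also gives loci, status flags and confidence bounds, and loci printed here are from it (mm9). Its status was OK for 22735 lines, LOWDATA for 282 and FAIL for 4. Its deposited bounds had a median half-width of 17.6% of the value at 1 to 5 FPKM, 8.22% at 5 to 20, 4.74% at 20 to 100 and 3.03% above. The depth in reads is unknown. Relative depth was read from genes under 0.1 FPKM, where ratios between libraries fell on ratios of small whole numbers (up to 6) within 1% for 76.4%, 79.6% and 79.4% of 1058, 1010 and 1113 genes. Correlations between libraries ran from 0.9904 to 0.9958, and none was a copy of another.

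Genes with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with an intensity trend in the variance moderation. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates those of low genes, and folds are ratios of mean FPKM. Where a value is called with the block, the replicate number was a covariate. The design text names 2 clones used in each condition, so libraries with the same number are taken as the same clone, which the titles do not state. The deviations of same-numbered libraries from their group means correlated at 0.215 across genes. P-values measure the spread between these libraries and clones only. Residual degrees of freedom were 2 without the block and 1 with it, to which moderation added 4.23 and 6.21. The median change of all tested genes was -0.0022.

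Gene lists, 26 in all, and the rule for named genes were fixed before the data were examined, as were the tests and most alternatives. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01, variance trend), with an estimated correlation and with fry, adjusted over the 24 lists. With an estimated correlation, camera had only the residual degrees of freedom, 2 without the block and 1 with it. Hardly any list could pass that way, so a miss there does not decide whether a list moved. The preset correlation was not estimated from these libraries. A first look with camera's default without that trend gave the same number of lists, 6. Each list has a count over all genes tested and a count adjusted over the list alone. The lists are p53 response, G2/M and mitosis, G1/S and DNA replication, cell cycle inhibitors, apoptosis, integrated stress response, interferon response, spermatogonial stem cell self-renewal, spermatogonial differentiation, retinoic acid response, meiotic prophase, spermatid genes, piRNA pathway and germ granule, RNA-binding proteins, pluripotency, nuclear-encoded respiratory chain, mitochondrial ribosome, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, housekeeping, the study's candidates, and markers of fibroblast feeders, Sertoli cells, Leydig and peritubular cells, and macrophages and blood. The named genes are Mir202, the 10 largest rises and 10 largest falls past the threshold, the study's candidates, up to 4 members with the largest change of each list and its members past the threshold (the 4 largest), and the most abundant marker of each cell type. Where fewer than 10 fell, places went to genes of at least 5 FPKM that fell in both pairs, ranked by the smaller pair change. Mdm2, Ei24, Cdc25b, Cenpf and Trp53 were added after their values were seen. The genes near Mir202 were added after the other results were seen but before their own values were, except that of Utf1, a member of the self-renewal and pluripotency lists.

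Seed sites were heptamers matching bases 2 to 8 of each arm, or bases 2 to 7 followed by A, in the longest annotated 3' UTR of a gene in GENCODE M21. That annotation served for symbols, 3' UTRs, lengths and GC content and for no coordinates. It matched 22131 of 22552 symbols and 11794 of 11924 tested genes (98.9%). Percentiles of list medians came from 10000 random lists matched on mean expression, and for the seed sites on 3' UTR length as well. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

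The scripts were tested on simulated data for 11924 genes, 200 of them changed. Changes were planted only in genes above about 5 FPKM, and each gene varied independently of the others. The shares recovered therefore do not describe low genes. Without the block, 66% of changes of 0.3 (log2), 98% of 0.5 and 100% of 1 and 2 were recovered, with 3.2% false among 188 calls. With the block, the shares were 48%, 92%, 98% and 100%, with 4.5% false among 177 calls. In the real libraries the block raised the number of calls, from 33 to 441, so these shares need not hold for them. A planted list was called and 0 of 24 random lists were. As the simulated genes varied independently, this does not test lists of co-regulated genes. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of 5 FPKM, quantile and median-of-ratios scaling, the highest locus of a symbol, the block, moderation without trend or robust, each library left out, a 2-fold threshold, and octamer or length-scaled sites. A library without a partner in its group was assumed to vary like the other group. Added after seeing the data were genes above 0 in every library, the block with the trend on length and GC removed, camera without variance trend, the heptamer comparison, and the genes within 500 kb of Mir202, with and without Utf1.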

Results

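RNA of mouse spermatogonial stem cells, the self-renewing germ cells at the base of sperm production, was sequenced to ask which transcripts change when the microRNA miR-202 is knocked out. The cells came from the testes of young DBA/C57 F1 males and carried an inducible knockout of miR-202. They were plated overnight on laminin and then kept for 2 days with 10 µg/ml doxycycline, the drug that induces the knockout, or without it. The labels name 2 single-cell clones per condition, so the comparison rests on 2 libraries with doxycycline and 2 without. All 4 libraries carry the genotype label wild type. The deposited values are FPKM, a fragment count scaled for transcript length and library size, for 22552 gene symbols, of which 11924 had a mean of at least 1 FPKM and were tested. The FPKM of a library summed to 313981 and 320243 with doxycycline and to 309153 and 314507 without. Read counts were not used here. Whole-number steps among the lowest values put the relative depths, in units of the doxycycline library of replicate 1, at 1.33 for its untreated partner, 1.22 for doxycycline replicate 2 and 1.55 for untreated replicate 2. The doxycycline library was thus the shallower of each pair.

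Mir202, the targeted gene, was listed at 0 FPKM in all 4 libraries. It lies on chromosome 7 at 147143588 to 147143659 (mm9). All 605 microRNA symbols in the files were listed at 0 in every library, so this value checks neither the knockout nor the labels. Protein-coding genes around the locus were measured. The 9 tested genes within 500 kb of Mir202 had a median log2 change with doxycycline of -0.31, and 8 of the 9 were lower in both pairs of same-numbered libraries. The medians were -0.24 in replicate 1 and -0.33 in replicate 2. Tubgcp2, a component of the microtubule-nucleating gamma-tubulin complex, had a log2 change of -0.44 ± 0.06 (SE), the mitochondrial beta-oxidation enzyme Echs1 one of -0.36 ± 0.06, and Utf1, a chromatin protein of undifferentiated spermatogonia, one of -0.30 ± 0.09. Inpp5a, Zfp511, Paox, Mtg1 and 1810014F10Rik lay between -0.21 and -0.49, and Caly, at -0.06, was the member that was not lower in both pairs. None of the 9 passed limma's test over all genes, where Tubgcp2 came closest with an adjusted p of 0.0578. With the replicate number as a block, 3 passed, namely Tubgcp2 (adjusted p = 0.00951), Echs1 (0.0294) and Utf1 (0.0479). Of 11698 windows of 9 neighbouring tested genes across the genome, none had a lower median. The lowest window that shared no gene with the 9 near Mir202 stood at -0.28, on chromosome 13 from 21813967 to 22127421. That stretch holds the histone genes Hist1h4j, Hist1h4k and Hist1h2an, which moved unevenly. Their log2 changes were -1.76, -0.02 and -1.40 in replicate 1 and 0.16, -0.92 and 0.32 in replicate 2. Lrrc27 and Syce1, which flank the genes near Mir202, had log2 changes of 0.21 and -0.02. The window of 500 kb was set after the other results were seen, that of Utf1 among them, but before the values of the other 8, whose median was -0.33.

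**Figure D1:**
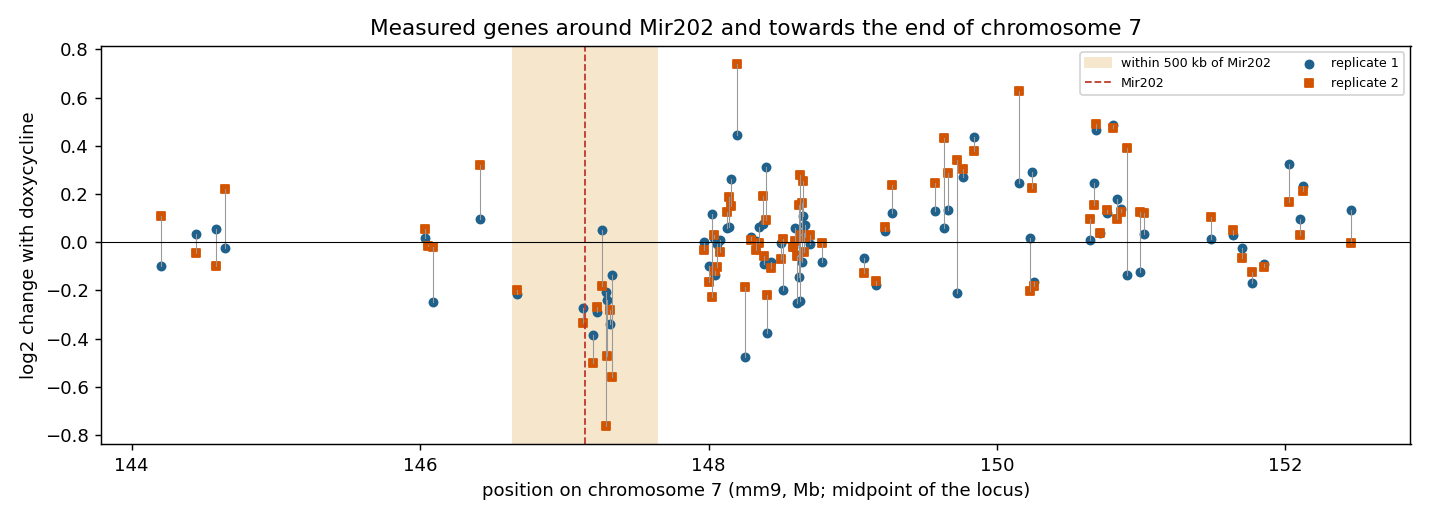
Log2 change with doxycycline of each tested gene on chromosome 7 from 144 Mb to the last tested gene, by position on mm9, with a point for replicate 1 and a point for replicate 2. The shaded stretch is the 500 kb on either side of Mir202, where 8 of the 9 genes lie below 0 in both replicates.

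With doxycycline more genes rose than fell. At an adjusted p under 0.05, 33 genes changed, 26 higher and 7 lower. At an unadjusted p under 0.05 there were 1799. Among the genes past the threshold, the largest rise was that of Ccng1, the cyclin G gene induced by p53, which went from 21.3 ± 3.31 FPKM without doxycycline to 60.8 ± 12.3 with it (SD, n = 2 each). That is 2.86-fold, with a log2 change of 1.47 ± 0.15 (SE) and a limma adjusted p of 0.0291 (chromosome 11, 40562054 to 40568788, mm9). Ddit4, a stress-induced inhibitor of mTORC1, rose 2.63-fold, Got1l1 2.74-fold, the pro-apoptotic BH3-only gene Bbc3 2.22-fold and the TGF-beta co-receptor Eng 1.99-fold. Cck, Sulf2, 4632434I11Rik, Gtse1 and Trp53inp1 filled the remaining places among the 10 largest rises, with log2 changes from 0.73 for Trp53inp1 to 0.84 for Gtse1, and the adjusted p of the 10 ran from 0.0288 to 0.0424.

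Among the 7 genes that fell, the long nuclear RNA Malat1 went from 61.2 ± 0.597 FPKM to 31.2 ± 2.36 (SD, n = 2 each), a log2 change of -0.95 ± 0.06 (SE) with a limma adjusted p of 0.00831 (chromosome 19, 5795690 to 5802671, mm9). Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 0.40 on the log2 scale, Prmt5, the arginine methyltransferase, by 0.39, and Zmym3 by 0.36. Their adjusted p were 0.0291, 0.0291 and 0.0488. The histone H4 gene Hist1h4n was at 3.66 and 3.42 FPKM with doxycycline and at 8.16 and 8.77 without (adjusted p = 0.017). It is summed over 2 loci, belongs to a family of near-identical copies, and lost its call when only the higher locus was kept. The snoRNA gene Snora78 was listed at 0 in both doxycycline libraries and at 1110 and 2289 FPKM without the drug (adjusted p = 0.00023). Its locus, chromosome 17 from 24856621 to 24856777 (mm9), lies inside Snhg9, which was listed at 0 in 3 libraries and at 63.9 FPKM in untreated replicate 2. Gm12166, a symbol on 2 loci, was listed at 0 with doxycycline and at 20.1 and 33.4 FPKM without (adjusted p = 0.00204). No fold is given for either. Dos, 1700015G11Rik and Tcf19, next in size of fall in both pairs, did not pass, with log2 changes of -0.49, -0.45 and -0.44. Their adjusted p were 0.0578, 0.209 and 0.0831, and 0.00909, 0.00936 and 0.0121 with the block.

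With the replicate number as a block, 441 genes passed, 325 higher and 116 lower, and all 33 were among them. The count without a block hung on single libraries: it was 60 without doxycycline replicate 1, 5 without doxycycline replicate 2, 5 without untreated replicate 1 and 2 without untreated replicate 2. Of the named genes that changed, only Snora78 and Gm12166 kept their call in each of these 4 fits. Ccng1 lost its call without doxycycline replicate 2 and without either untreated library, and also under robust variance moderation.

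**Figure D2:**
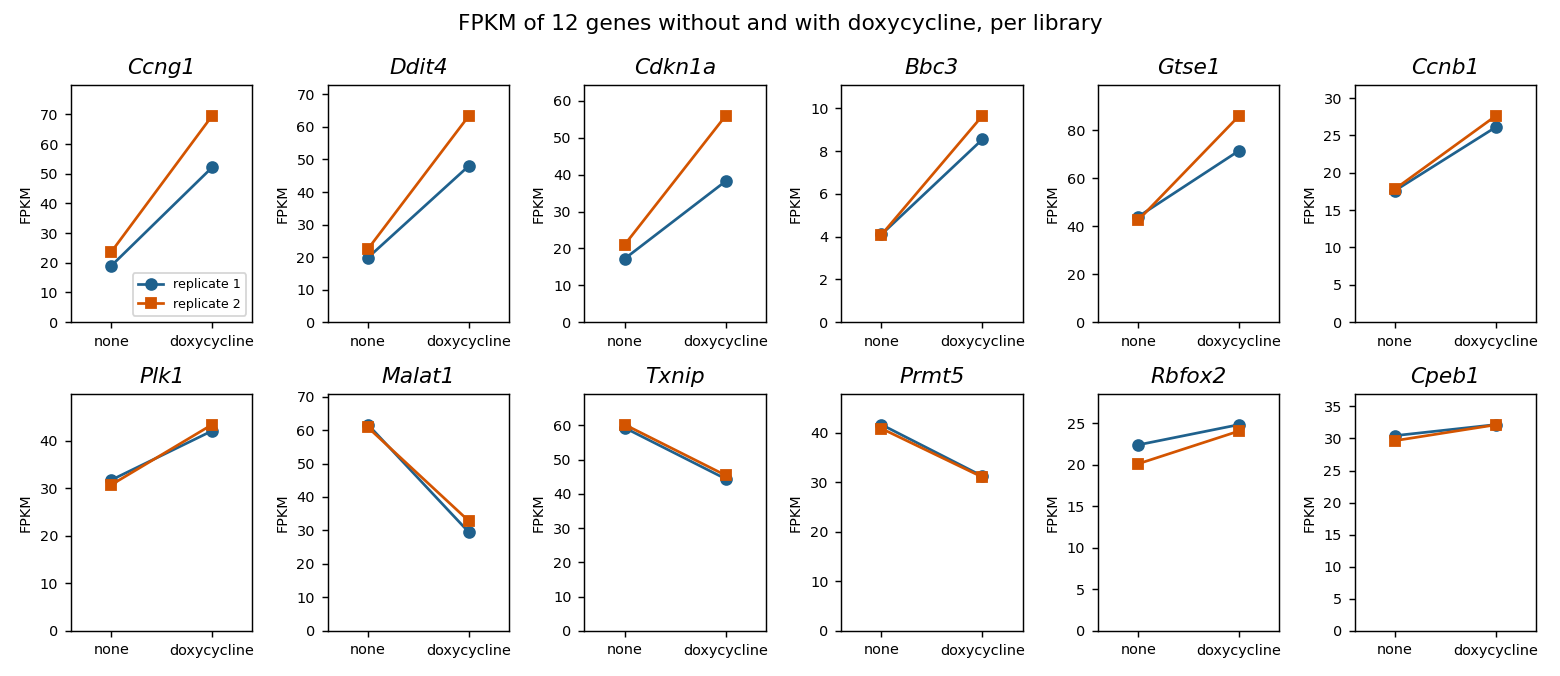
FPKM of 12 named genes in each of the 4 libraries, with 1 panel per gene and the vertical axis starting at 0. Ccng1, Ddit4, Cdkn1a, Bbc3, Gtse1, Ccnb1, Plk1, Rbfox2 and Cpeb1 are higher and Malat1, Txnip and Prmt5 lower in both doxycycline libraries than in both untreated libraries. Rbfox2 and Cpeb1, at log2 changes of 0.20 and 0.09, did not pass the threshold.

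Targets of p53, the transcription factor that halts the cycle and triggers apoptosis after stress, rose as a group. Of 35 measured members, 7 rose over all genes tested and 23 rose adjusted over the list alone, and none fell. The 7 were Ccng1, Bbc3, Gtse1, Trp53inp1, Sesn2, the p53 ubiquitin ligase Mdm2 (1.34-fold, adjusted p = 0.0291) and Ei24 (log2 change 0.48, adjusted p = 0.0460). The list's median log2 change was 0.41, at 0.38 in replicate 1 and 0.50 in replicate 2, and 30 of the 35 members were higher in both pairs against 2 lower. Camera's adjusted p was 4.28e-22, against an adjusted p of 0.512 with an estimated correlation.

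Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, stood at 47.1 ± 12.6 FPKM with doxycycline (SD, n = 2), a mean 2.46-fold that of the untreated libraries. Its log2 change was 1.24, which missed the threshold (adjusted p = 0.0636, and 0.000289 with the block). Plk2 and Psrc1, both at 1.22, missed it as well (0.0522 and 0.0530) and passed with the block (0.000289 and 0.000407), under which 23 members passed. Trp53 itself was at a log2 change of 0.08 (adjusted p = 0.369). Of the 24 cell cycle inhibitors measured, Ccng1 rose, and adjusted over the list alone 3 rose and 1 fell. Their median was 0.03 and camera's adjusted p was 0.125. The antiproliferative gene Btg2 was at 0.47 (adjusted p = 0.0580, block 0.00734) and Gadd45g at -0.34 (0.197, block 0.0244). Of 25 apoptosis genes, Bbc3 rose, and 5 rose adjusted over the list alone. Pmaip1, Tnfrsf10b and Apaf1 had log2 changes of 0.72, 0.56 and 0.56 and passed only with the block (adjusted p = 0.00372, 0.00157 and 0.00909, against 0.0767, 0.0697 and 0.0818). The apoptosis median was -0.01 while its mean was 0.13 and camera's direction was up (adjusted p = 0.0702). Under fry with the block, apoptosis was the only list to pass (adjusted p = 0.0351).

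Genes of G2 and mitosis rose as a group, while those of the G1/S transition and DNA replication did not. All 50 measured G2/M genes were higher with doxycycline in both pairs. Cyclin B1 (Ccnb1) rose 1.52-fold, from 17.7 ± 0.153 to 26.9 ± 1.07 FPKM (SD, n = 2 each), cyclin B2 (Ccnb2) 1.46-fold, the mitotic kinase gene Plk1 1.37-fold and Gtse1, a microtubule-binding protein of G2 that restrains p53, 1.82-fold, each with a limma adjusted p of 0.0291. Cdc25b and Cenpf, both at 1.37-fold, brought the members that rose to 6 (adjusted p = 0.0334 and 0.0291), 47 rose adjusted over the list alone, 35 passed with the block and none fell. The median log2 change was 0.29, at 0.25 in replicate 1 and 0.30 in replicate 2. Camera's adjusted p was 1.64e-39, against an adjusted p of 0.512 with an estimated correlation. The kinase gene Aurka was at 0.48 and missed the threshold (adjusted p = 0.0597, block 0.00277). The p53 and G2/M lists share Gtse1 and Ckap2, and together they hold 12 of the 26 genes that rose. None of the 46 G1/S and replication genes passed, also when adjusted over the list alone. Their median was -0.02 and camera's adjusted p was 0.386. Ccne2, Chaf1b and Ung had log2 changes of -0.23, 0.21 and -0.16, none past the threshold. The medians of Sertoli markers (0.16), feeder fibroblast markers (0.15), macrophage and blood markers (0.11) and cytosolic ribosomal protein genes (0.10) had the same sign as those of the p53 and G2/M lists.

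**Figure D3:**
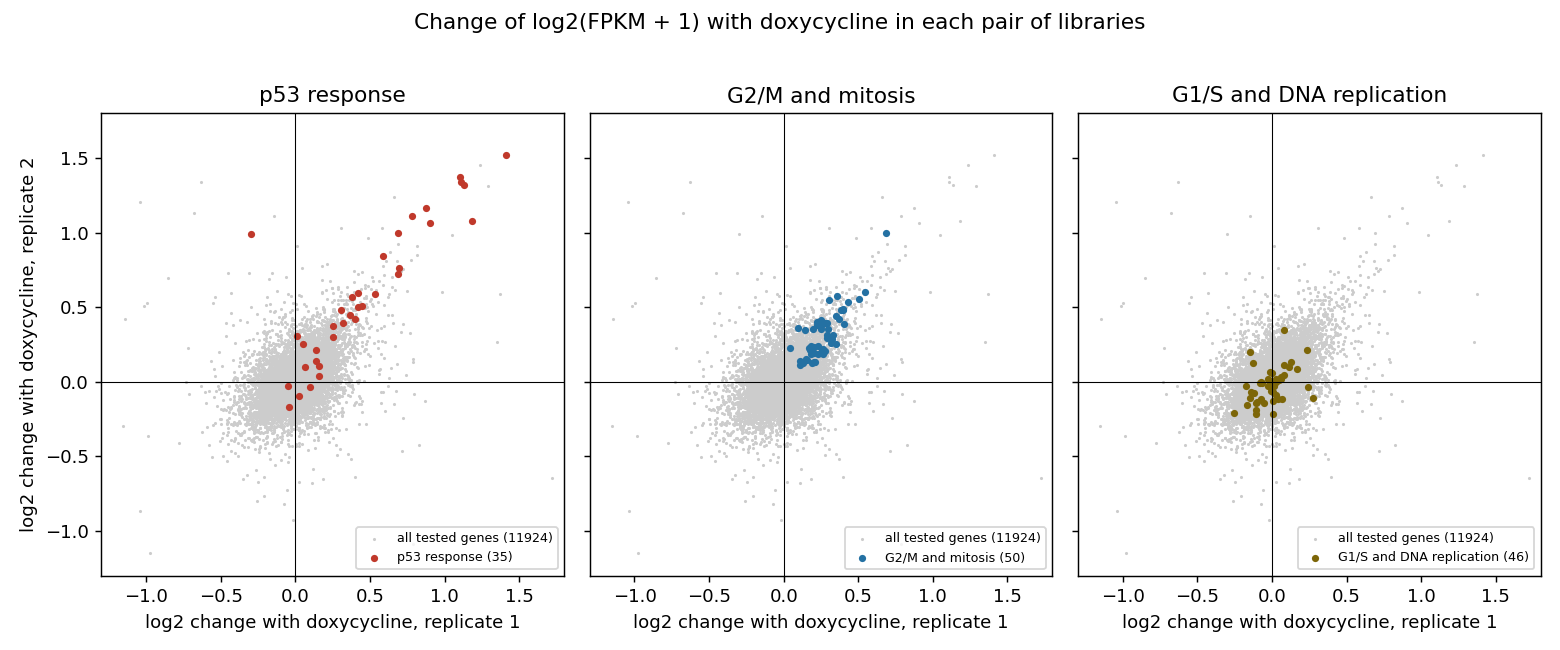
Log2 change with doxycycline in replicate 1 (horizontal) against replicate 2 (vertical) for every tested gene in grey, with the members of the p53, G2/M and G1/S lists in colour in 3 panels; 11 genes lie outside the axes, none of them a list member. All 50 G2/M genes and 30 of the 35 p53 genes lie above 0 on both axes, while the G1/S genes scatter around 0.

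The series title ties miR-202 to cell cycle regulators and RNA-binding proteins. The 16 candidates, chosen from what is known of the study, were all measured. Beside such genes they include Stra8 and Dmrtb1 of the differentiation list and Dmc1, Sycp3 and Rec8 of the meiotic prophase list. None of the 16 passed over all genes tested. Adjusted over the list alone 2 rose, which is not independent evidence because the study drew on these samples. The list's median was 0.06 (camera adjusted p = 0.114). With the block 3 rose, namely cyclin A2 (Ccna2), at a log2 change of 0.33 (adjusted p = 0.00795, against 0.0576 without it), cyclin D1 (Ccnd1), at 0.22 (0.0334 against 0.105), and the meiotic cohesin Rec8, at 0.31 (0.0399 against 0.229). The RNA-binding proteins Rbfox2 and Cpeb1 were at 24.5 ± 0.546 against 21.3 ± 1.61 FPKM and at 32.1 ± 0.0212 against 30.0 ± 0.553 FPKM (SD, n = 2 each). Their log2 changes were 0.20 and 0.09, with limma adjusted p of 0.238 and 0.346. Stra8, Sycp3 and Dmc1, genes of meiotic entry and recombination, lay between 0.11 and 0.13 and passed in neither fit. The same held for Ccnd2 at -0.16, Dmrtb1 and Cdk4 at -0.13, Ccne1 at -0.10, E2f1 at -0.04, Dazl at 0.01, and Cdk2 and Cdk6 at 0.03.

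No gene of stem cell self-renewal or of spermatogonial differentiation passed over all genes tested. Of 38 measured self-renewal genes, none rose and 2 fell adjusted over the list alone, with a median of -0.02 and a camera adjusted p of 0.234. With the block Plvap rose and 6 fell, namely Nanos3, Egr3, Egr4, Utf1, Mycn and Glis3. Nanos3 was at a log2 change of -0.30 (block adjusted p = 0.0413, against 0.212) and the immediate-early gene Egr3 at -0.29 (0.0414 against 0.131). The mesodermal factor gene T was at 0.43 (adjusted p = 0.196). Of 24 differentiation genes, adjusted over the list alone 3 rose and 1 fell. Their median was -0.002 while the mean was 0.04 and camera's direction was up (adjusted p = 0.301). Ly6k was at 0.59 and Sox3, an early spermatogonial factor, at -0.34, both past the threshold only with the block (0.0159 and 0.0219, against 0.0815 and 0.151), and Lmo1 at -0.26 passed in neither fit.

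Genes of the retinoic acid response were higher as a list, with a median of 0.13 over 13 genes and 7 of them higher in both pairs. Of the cell type lists, Sertoli (0.16) and feeder fibroblast markers (0.15) had larger medians. That of the macrophage and blood list was 0.11 and that of the 2 Leydig and peritubular markers -0.15. Camera's adjusted p was 0.0477, against an adjusted p of 0.512 with an estimated correlation. No member passed over all genes, and 2 rose adjusted over the list alone. The retinaldehyde dehydrogenase Aldh1a3 was at 0.41 (adjusted p = 0.160, block 0.0462), the retinaldehyde reductase Dhrs3 at 0.28 and the retinoic acid carrier Crabp2 at 0.25 (0.165 and 0.432). The list lost its call without doxycycline replicate 2, without untreated replicate 2, with no expression filter and with one of 5 FPKM. Over the 14 settings that refit camera with the preset correlation, its lowest median was 0.035 and its highest adjusted p 0.256.

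Among meiotic and later germ cell genes, none of 36 meiotic prophase genes passed by either adjustment, with a median of 0.007 (camera adjusted p = 0.483). Spata22, Hspa2 and Spo11 were at -0.46, 0.32 and 0.26. Of 5 spermatid genes none passed either, with a median of 0.13 (camera adjusted p = 0.125), Ldhc was at 0.40 (adjusted p = 0.219, block 0.0448), and Tnp1, Odf2 and Tekt1 lay between 0.12 and 0.13. None of 24 piRNA and germ granule genes passed, with a median of -0.01 (0.473), Gtsf1 at 0.25 (0.159, block 0.0189), Pld6 at -0.22, Tex19.1 at -0.11 and Piwil1 at -0.10. Of 71 RNA-binding protein genes none passed over all genes and 1 rose adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.359). With the block, 1 rose and 4 fell. Mbnl2, a splicing regulator, was at 0.42 (0.0701, block 0.0117), Mex3d at -0.29 (0.160, block 0.0302) and Ybx2 at -0.27 (0.364). None of 9 pluripotency genes passed. Their median was -0.03, their mean 0.01 and camera's direction up (0.964), with Klf5 at 0.30, Klf2 at 0.18, Dppa5a at 0.14 and Utf1 at -0.30 (block adjusted p = 0.0479, against 0.215).

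Among stress genes, Ddit4 and Sesn2 stood out. Of 37 genes of the integrated stress response, the program set off by phosphorylation of eIF2, these 2 rose, 3 rose adjusted over the list alone, and the median was 0.0001 (camera adjusted p = 0.609). Ddit3 (CHOP) was at 0.31 (adjusted p = 0.111, block 0.0243) and Nupr1 at -0.21. Interferon response genes did not pass, with 20 measured, 3 that rose adjusted over the list alone, a median of 0.01 and a camera adjusted p of 0.0949. Ifi35, Ifitm3, Bst2 and Gbp3 were at 0.62, 0.59, 0.47 and 0.35, the first 3 past the threshold only with the block (0.0135, 0.00669 and 0.00171, against 0.0724, 0.0718 and 0.181). The 73 nuclear genes of the respiratory chain were higher as a list, by a median of 0.03, with 39 higher in both pairs, 14 lower, and no member past the threshold by either adjustment. That median stood at percentile 77.0 among random lists matched on expression. Camera's adjusted p was 0.00949, against an adjusted p of 0.512 with an estimated correlation, and the call was lost without doxycycline replicate 2, without untreated replicate 1, with quantile normalization and with length and GC removed. Over the 14 settings that refit camera with the preset correlation, the median ran from 0.003 to 0.06, and the highest adjusted p was 0.422. Ndufb4, Ndufa12, Cox7a2 and Ndufb2 were at 0.40, 0.27, 0.19 and -0.18, with Cox7a2 past the threshold under the block (0.0474, against 0.234). Of 76 mitochondrial ribosome genes none passed over all genes, 1 fell adjusted over the list alone, and the median was 0.01 (0.473). Mrps34 was at -0.36 (0.0724, block 0.0164), Mrps6 at 0.26 and Mrpl33 at 0.22, both past the threshold under the block only (0.0406 and 0.0229, against 0.221 and 0.214), and Mrpl48 at 0.24. None of the mitochondrially encoded genes was measured.

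Cytosolic ribosomal protein genes were higher as a list, with a median of 0.10 over 68 genes, 39 of them higher in both pairs and 11 lower. No member passed over all genes and 2 rose adjusted over the list alone, while with the block 5 rose and 2 fell. Camera's adjusted p was 0.00110, against an adjusted p of 0.512 with an estimated correlation and 0.188 without doxycycline replicate 2. Over the alternatives the median ran from 0.04 to 0.15. Rps26 was at 0.55 (adjusted p = 0.196, block 0.000866), Rpl30 at -0.47 (0.149, block 0.0190) and Rps29 at -0.67. Rpl35 stood at 107 FPKM in doxycycline replicate 2 and at 1.78, 1.91 and 2.58 FPKM in the others. None of 30 histone genes of the list passed, and their median of 0.008 differed in sign from their mean of -0.05 and from camera's direction, which was down (0.359). Hist1h4j, Hist1h2an, Hist1h4k and Hist1h4c were at -0.80, -0.54, -0.47 and 0.45. Of 16 housekeeping genes none passed, with a median of 0.07 (0.0622), B2m at 0.21, Tubb5 at 0.16, Gusb at 0.15 and Gapdh at -0.14.

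Of the markers of other cell types, the fibroblast feeder list was higher with doxycycline, with a median of 0.15 over 27 genes, 16 of them higher in both pairs and 6 lower. Camera's adjusted p was 0.0250, against an adjusted p of 0.512 with an estimated correlation. The gelatinase Mmp2 rose 1.51-fold (limma adjusted p = 0.0478) and 3 rose adjusted over the list alone, while Col1a1, the most abundant marker, stood at 41.0 ± 2.56 against 36.7 ± 6.02 FPKM (SD, n = 2 each), a log2 change of 0.16 (adjusted p = 0.506). Ccl2, Acta2 and Thbs2 were at 0.39, -0.37 and 0.33. The list lost its call without doxycycline replicate 1, without untreated replicate 2, where its median was -0.0038, and with a filter of 5 FPKM. Of 9 Sertoli markers, Trf, the transferrin gene, rose 1.27-fold (adjusted p = 0.0478), also adjusted over the list alone. The Sertoli median was 0.16, its camera adjusted p 0.0565 and 0.0379 with the block, against an adjusted p of 0.632 with the block and an estimated correlation. Ctsl, the most abundant Sertoli marker, was at 131 ± 7.22 against 117 ± 2.56 FPKM (SD, n = 2 each), and Inhbb, Sox9 and Clu at 0.27, 0.26 and 0.24. Of 6 measured genes of the macrophage and blood list, which also holds endothelial genes, none passed, with a median of 0.11 (0.301). The most abundant, the endothelial gene Cdh5, was at 5.24 against 4.97 FPKM. Kdr, also endothelial, Hba-a1 and Cd68 were at 0.28, 0.23 and 0.15. Leydig and peritubular cells had 2 measured markers, too few for a test, Actg2 at -0.36 and Des, the more abundant, at 0.07.

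**Figure D4:**
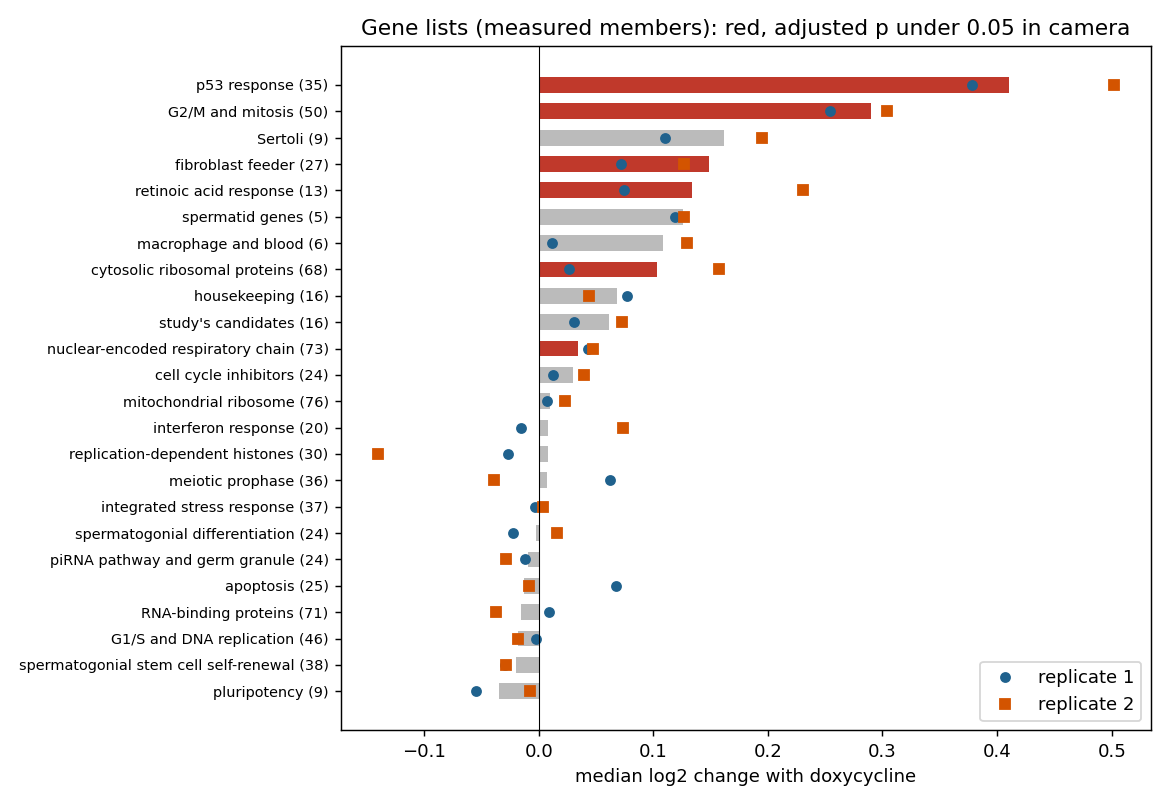
Median log2 change with doxycycline of the 24 lists with at least 5 measured genes, as bars from 0, with points for the median in replicate 1 and in replicate 2. Red bars mark the 6 lists at a camera adjusted p under 0.05 with the preset correlation, none of which passed with an estimated correlation; the p53 and G2/M lists have the largest medians, 0.41 and 0.29.

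Across the 24 lists tested, 6 passed with the preset correlation and 7 with the block, which added Sertoli markers. With an estimated correlation none passed, at a smallest adjusted p of 0.512 (0.632 with the block), and 1 list lay at an unadjusted p under 0.05. That list was G2/M, at a camera p of 0.0403, although all 50 members were higher in both pairs. With 2 residual degrees of freedom (1 with the block), a miss in this test does not count against a list. Fry, which asks whether the genes of a list move on balance one way, passed none, with 5 lists at an unadjusted p under 0.05. The count of 6 fell to 3 without doxycycline replicate 2. The block also moved counts of single genes past the threshold, to 3 up and 1 down among cell cycle inhibitors and among differentiation genes, 5 up for apoptosis, 4 for fibroblast feeders, 3 for the interferon response and 2 for each of the retinoic acid response and the respiratory chain. It gave 2 up and 1 down for the mitochondrial ribosome, 1 up for each of the meiotic, spermatid, piRNA and G1/S lists, and 1 down for histones and for pluripotency.

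Transcripts with miR-202 seed sites in their 3' UTR were not shifted past the threshold against those without. Of 11526 tested genes with an annotated 3' UTR, 1619 (14%) had a heptamer site for miR-202-3p and 1811 (15.7%) for miR-202-5p. Their median log2 change lay below that of genes without a site by differences of -0.0086 and -0.013, with a camera adjusted p of 0.403 for both arms. Among random lists matched on 3' UTR length and mean expression the medians stood at percentiles 46.5 and 13.2. The 323 and 381 genes with an octamer site differed by -0.0097 and -0.012. A comparison added later used the mean difference between genes with and without a site. For it, log2 changes were clipped at percentiles 1 and 99 and adjusted for 3' UTR length and expression. That difference was -0.0015 for the 3p arm and -0.0031 for the 5p arm. Of all 15666 ranked pairs of heptamers, 10503 had a higher value than the 3p arm and 11823 a higher one than the 5p arm. Of genes with a site, 3 rose for the 3p arm, and 4 rose and 1 fell for the 5p arm.

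By size alone, 41 genes changed at least 1.5-fold in FPKM + 1 the same way in both same-numbered pairs, 37 higher and 4 lower. Against these, 7 changed as much in opposite directions. At a pseudocount of 0.1 FPKM these counts were 62 and 17, at 0.5 FPKM 46 and 12, and with a filter of 5 FPKM 31 and 2. No test stands behind these counts. Across genes, which are not independent replicates, the changes of the 2 pairs correlated at 0.574. The standard deviation across genes of the change with doxycycline was 0.191 in replicate 1 and 0.218 in replicate 2, against 0.154 between the doxycycline libraries and 0.149 between the untreated ones. Snora78 (-10.1 in replicate 1, -11.2 in replicate 2) and Gm12166 (-4.40 and -5.10) weigh heavily on the correlation and on the spread of the doxycycline changes. Neither was recomputed without them, so these figures do not describe a shift of most genes. The replicate numbers differed at 18 genes by limma with treatment as a term, 9 higher and 9 lower in replicate 2. At an unadjusted p under 0.05 there were 1568. Both counts are from the fit with the block, in which doxycycline changed 441 genes, and not from the one that gave 33. Ccng1, the largest rise past the threshold with doxycycline, was among the 9 higher in replicate 2, by 0.36 (limma adjusted p = 0.0454). Tcf15 was higher in replicate 2 by 0.56 on the log2 scale (adjusted p = 0.00651) and Gsg1 lower, at -1.13 (adjusted p = 0.0123). Col6a1 and Col6a2, collagens of the fibroblast list, were at -0.61 and -0.52 (0.0454 and 0.0407). The genes named here for the replicate numbers were chosen after their values were seen.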

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

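The tests of explanations in this part were chosen only after the results they bear on were seen.

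In 7 genes the change with doxycycline was at least 1.5-fold in FPKM + 1 in both pairs of same-numbered libraries but in opposite directions. This difference between pairs was not tested. The log2 change in replicate 2 minus that in replicate 1 was 2.25 for DXBay18, 1.81 for Hba-a1, 1.55 for Rex2 and 1.97 for S100z, and it was -2.54 for Gm14685, -2.37 for Rhox3e and -1.87 for Rmrp. Most were low. Rmrp, the RNA of RNase MRP, was at 62.7 and 25.4 FPKM with doxycycline and at 35.9 and 55.1 without, in the order of the replicates.

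The rise of p53 targets, by a median of 0.41 on the log2 scale, was set against 4 other explanations. With the trend on transcript length and GC content removed and the replicate block kept, the median was 0.403, which argues against such a trend as the whole cause. RNA of feeder fibroblasts would bring their most abundant transcripts, yet the 5 most abundant fibroblast markers had a median of 0.164, and each of them lay below the p53 median (Col1a1 0.16, Col5a1 -0.02, Sparc 0.11, Fstl1 0.29, Bgn 0.26). A stress response of the integrated kind would raise its 36 genes outside the p53 list, whose median was -0.0058. Doxycycline itself cannot be told apart from the knockout, because 0 libraries hold doxycycline without the inducible knockout, and p53 activity after loss of miR-202, or after DNA breaks if the knockout cuts DNA, which the labels do not state, may each account for the rise.

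The rise of G2/M genes without G1/S genes was weighed in the same way. A general rise of proliferation genes would raise the 46 G1/S and replication genes too. Their median was -0.0177, with 12 higher and 17 lower in both pairs. With each library left out it ran from -0.0315 to 0.007. These values argue against a general rise for the genes of these 2 lists. They are part of the pattern, as is the difference of 0.308 between the medians, and no separate test. With the trend on length and GC removed and the block kept, the G2/M median was 0.266, which argues against that trend as the whole cause. A larger share of cells in G2 and mitosis stays open, as the 100% of the 50 genes that were higher in both pairs restates the pattern. RNA levels do not separate a larger share of cells from more RNA per cell, and no measure of cell cycle phase or cell number was analysed here, so this stays a hypothesis, with doxycycline itself open as well.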

How the results depend on the processing

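The fits without genes at 0, with the block and the length and GC trend removed, and without camera's variance trend, and all fits for the genes near Mir202, were chosen only after the results were seen. The number of genes changed, 33, was 1 with no filter, 88 with a mean of 5 FPKM, where fewer genes are tested, 2 without the variance trend, 441 with the replicate block, 598 with the block and the length and GC trend removed, and 2 to 60 with 1 library left out. The other settings gave 31 to 48. The 6 lists became 0 with an estimated correlation, 0 with fry and 3 to 6 with 1 library left out. The p53 and G2/M lists passed in all 14 settings that refit camera, with medians of 0.38 to 0.54 and 0.25 to 0.31. The 41 genes changed in both pairs were 62 at a pseudocount of 0.1 and 11 at a 2-fold threshold. The 18 genes that differ between replicate numbers were 108 and 56 at pseudocounts of 0.1 and 0.5, 0 with no filter, 136 at 5 FPKM and 3 with quantile normalization. Apart from calls printed beside their values in the report, the block changed none of the calls on lists and named genes.

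Of the list medians under all alternatives, 281 kept sign and side of the threshold, 10 passed it newly, 11 no longer passed and 31 changed sign; of the named genes, 1666, 110, 112 and 15. Apart from the fibroblast feeder list, no value that changed sign was past the threshold in the report. The cause was not tested for any of these. With the block and the length and GC trend removed, the miR-202-3p difference was 0.0005 and the medians 0.026 for differentiation, -0.0021 for meiotic prophase, -0.0049 for the mitochondrial ribosome and -0.0004 for histones, and Dazl was at -0.0204. With at least 1 site per kb, the miR-202-3p difference was 0.0036. With no filter, the medians were 0.003 for differentiation, 0.0282 for apoptosis, -0.0017 for histones and 0.0054 for pluripotency. At 5 FPKM they were 0.0005 for apoptosis and -0.0058 for the integrated stress response, which was at -0.0162 with quantile normalization, where Dazl was at -0.041.

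With each library left out in turn, the medians ran from -0.0537 to 0.0009 for self-renewal, -0.0065 to 0.0433 for differentiation, -0.0141 to 0.0427 for meiotic prophase, -0.048 to 0.0028 for piRNA genes, -0.0403 to 0.0037 for RNA-binding proteins, -0.0315 to 0.007 for G1/S, -0.0096 to 0.055 for cell cycle inhibitors, -0.0289 to 0.0245 for apoptosis, -0.0062 to 0.0114 for the integrated stress response, -0.0903 to -0.0006 for histones, -0.0843 to 0.0158 for pluripotency and -0.0038 to 0.2278 for fibroblast feeders. The log2 changes ran from -0.2481 to 0.0476 for Ccne1, -0.1582 to 0.21 for Cdk6, -0.0287 to 0.0477 for Dazl, -0.0318 to 0.1672 for Des, -0.2874 to 0.0197 for Dmrtb1, -0.2858 to 0.0102 for Gapdh, -0.4509 to 0.9067 for Hba-a1, -0.4531 to 0.0403 for Nupr1 and -0.2173 to 5.0608 for Rpl35, which rests on doxycycline replicate 2. The doxycycline libraries are the shallower of each pair, and the confidence bounds of the authors, which widen below 5 FPKM, limit the low genes most.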

Other observations

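The tests of loss of the chromosome arm, of length and GC content and of short gene models were chosen only after the result was seen; those of breaks near Mir202 and of nuclear RNA were written down before, though Utf1, 1 of the genes near Mir202, had been seen with the gene lists.

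Of the 26 genes that rose, 6 have not been named so far, and they were picked out here after their values were seen. Kifc1, a mitotic kinesin, rose by 0.71 on the log2 scale, the centromere protein Cenpm by 0.66, the thiamine transporter Slc19a2 by 0.58, Arl6ip1 by 0.52 and the collagen Col13a1 by 0.38 (limma adjusted p from 0.0291 to 0.0437). Igf2, the imprinted fetal growth factor gene near the end of chromosome 7, rose by 0.41 (adjusted p = 0.0334).

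Genes beside Mir202 were lower with doxycycline, by a median of -0.31 over 9 genes, and their median stood at percentile 0 of the 11698 windows of as many neighbouring genes, where breaks at the locus would put it at or under the 5th. The position was the same in replicate 2 alone (percentile 0) and nearly so in replicate 1 alone (percentile 0.03). Over 16 alternatives the median ran from -0.39 to -0.14, with a highest percentile of 0.0851, and without Utf1 it was -0.33, at percentile 0. Loss of the chromosome arm beyond the locus is argued against by the 69 genes from 500 kb beyond it to the end of chromosome 7, whose median was 0.0376, and a trend on length and GC by a percentile of 0 once it was removed with the block kept. A local effect of the induced edit, such as breaks if the knockout cuts DNA, or loss of a regulatory element, is a candidate explanation that these data do not separate, and no doxycycline library without the knockout was analysed here.

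Lower recovery of nuclear RNA could account for the fall of Malat1, but 5 other nuclear long RNAs (Neat1, Meg3, Rian, Mirg and Tug1), of 10 in the list, had a median change of 0.153, which argues against it. Unstable estimates for short gene models may account for Snora78 and Gm12166 being listed at 0: of 731 symbols with a locus under 250 bases, 4 reached 1 FPKM in some library. Of these, 2 are the genes in question, and of the other 2, Scarna6 and Rn4.5s, 1 (50%), Scarna6, was at 0 and at 2.84 FPKM within the doxycycline libraries, too few to decide.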
